A study of Homo sapiens with 12 samples.

How the data were processed

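Total RNA of SH-SY5Y, a human neuroblastoma cell line, was measured on Affymetrix Human Transcriptome Array 2.0 arrays. Per the labels, cells in medium with 15% serum were electroporated at 1100 V for 50 ms with an siRNA against MATR3 (Matrin3, a nuclear protein that binds RNA and DNA) or with a negative control siRNA. RNA was taken 48 h later and 100 ng was used as input. There were 3 replicates per group, each summarised by the authors at gene level (transcript clusters) and at exon level (exon and junction probe sets). The gene-level and exon-level tables share 2995 features, and all 2995 held identical values in every sample, so both tables were read as summaries of the same arrays and were never pooled. The labels do not say that the replicates came from separate cultures, so every p-value measures only the spread between these samples, which may be technical.

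The deposited values are log2 signals. Per the submitters' processing notes they come from Affymetrix Expression Console and RMA, with no version, order of steps, annotation release or genome build given. The 6 arrays did not share one distribution, with gene-level medians from 4.80 to 5.16, and nothing was rescaled before the tests. Array depth has no count, and the number of arrays limits the precision.

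Gene symbols came from the platform annotation and were updated through gene identifiers or older symbols. Of 67528 transcript clusters, 23781 had 1 gene symbol, 1543 had several and 42204 had none. Of those with 1 symbol, 21497 were set through the gene identifier, 1974 were current, 306 were updated from an older symbol and 4 were kept as given. Of 913055 probe sets, 672085 had 1 symbol, 39483 had several and 201487 had none. Genes were named only from features with 1 symbol, except for the MATR3 cluster, which the annotation gives to both MATR3 and SNHG4. A table of RefSeq genes on GRCh38.p14 was used only for names and for which genes are neighbours, and no coordinates are given.

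Tests ran in R 4.3.3 with limma 3.58.1, and the data.table package (version 1.17.8) read the files. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The choices fixed before the data were examined were as follows. Linear models (lmFit and eBayes, two-sided) compared MATR3 siRNA with control siRNA, 3 samples against 3, with no block. They covered the 33782 transcript clusters and, separately, the 456623 probe sets whose mean over the 6 samples was at or above the median of all. The Benjamini-Hochberg adjusted p threshold was 0.05. The splicing index of a probe set was its log2 value minus the mean over the kept probe sets of its gene in the same sample, for genes with 1 symbol and at least 5 kept probe sets, 347254 probe sets in all. A total of 22 gene lists were tested with camera at a preset correlation of 0.01, with 1 cluster per gene and the clusters with 1 symbol as background. Camera with an estimated correlation and fry stand beside it.

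The lists were PTB, hnRNP and paraspeckle proteins, SR proteins and splicing regulators, genes linked to amyotrophic lateral sclerosis (ALS), sympathoadrenal identity, mesenchymal neuroblastoma state with Schwann or fibroblast markers, neuronal cytoskeleton and axon growth, synapse and vesicle release, DNA replication and G1/S, G2/M and mitosis, replication-dependent histones, p53 targets, interferon response, unfolded protein and ATF4 response, cholesterol synthesis and uptake, hypoxia and glycolysis, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, nonsense-mediated decay factors and targets, immediate early genes, TGF-beta and BMP targets with extracellular matrix, Wnt pathway, and autophagy and lysosome. A further list held 9 genes recalled from earlier published work on MATR3-dependent exons. That work may include these samples, so this list is not independent evidence.

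The rule for named genes took the 10 highest and 10 lowest changes among called clusters with 1 symbol whose groups did not overlap. It left out small RNAs by the start of the symbol (SNOR, MIR, RNU, RNY, RN7, SCARNA or VTRNA), which does not cover the SNAR genes. In each list it took up to 4 called members with the largest change, or the 2 brightest members where none was called. Because the fixed model called no cluster, this rule named no gene. The same rule was then applied to an added model, with the same sign in all 3 pairs in place of groups that do not overlap. Every call of the added model met this condition, so it removed none. Splicing index calls of the added model are all named, and so are the few other features mentioned outside the rule, which were chosen after their values were seen.

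The replicate numbers in the labels are shared by both groups. Deviations from the group means correlated between samples of the same number at 0.696, 0.327 and 0.527, all above 0.1, so the numbers were taken to pair the samples, and changes are given as the mean and SD of 3 pair differences. This check sets replicate 1 apart but cannot show how replicates 2 and 3 match, since they also correlated when crossed, at 0.507 and 0.389. Their matching follows the numbers in the labels alone. Mean changes do not depend on it, but the SDs of pair differences and the signs of single pairs do. The replicate 1 pair stood apart from the other 4 arrays. Principal component 1 held 78.2% of the variance and separated it, and still held 51.2% after quantile normalization. The labels give no batch. This split is called the array set here, and it holds 1 sample of each group against 2 of each.

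Models with the array set as a block were added after the data were examined. One covers the 15209 kept clusters with 1 gene symbol. Another covers the splicing index over 195458 exon probe sets, without junctions, with an intensity trend and robust eBayes. Before they were chosen, 30 models of the transcript clusters and 24 of the splicing index had been looked at, differing in block, filter, feature set and eBayes options. Of the 30, 13 gave 0 calls, 12 gave at least 100 and the highest gave 1122. Of the 24, 15 gave 0 calls and the highest gave 17. Calls of the added models were therefore picked with knowledge of the counts.

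The models were tested on simulated data, with 5 simulations of 200 changed features each and variances drawn from the fitted prior, which assumes that the model holds. Over 33782 clusters with no block, 0% of 2-fold, 28.0% of 4-fold and 91.0% of 16-fold changes were recovered. Over 15209 clusters with 1 symbol and the array set as a block, 74.0% of 1.5-fold and 94.0% of 2-fold changes were recovered, and 4.93% of calls were false. Over 195458 exon probe sets, the added splicing index model recovered 0.5% of 2-fold, 46.0% of 4-fold and 97.0% of 16-fold changes. Only 1 run simulated lists, with 20 random lists of genes that varied independently. The 1 list of 30 members shifted by 0.2 log2 was called and none of the others was. In the data, members of some lists varied together, with an estimated correlation of 0.26 for hypoxia and glycolysis and 0.22 for sympathoadrenal identity. The simulation therefore does not test for false calls of such lists.

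Alternatives covered the filter on dim features, intensity trend and robust eBayes, repeated quantile normalization, median centring, array weights, the replicate number as a block, each sample left out in turn, a 1.5-fold minimum, clusters with 1 symbol, other set tests, diffSplice and other gene values in the splicing index. The array set block and the use of replicates 2 and 3 alone were added later. A total of 2995 gene-level features that are no transcript cluster and 1530 exon-level features that are no probe set were left out, except that 23 background probe sets gave the background signal.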

Results

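The series measured gene expression and exon-level signal in SH-SY5Y cells 48 h after electroporation with MATR3 siRNA or negative control siRNA, with 3 samples in each group. Its title names splicing pattern and gene expression level as the objects of the knockdown. The median log2 signal over transcript clusters was 5.10, 4.99 and 4.93 in MATR3 siRNA replicates 1 to 3 and 5.16, 4.80 and 4.83 in the control replicates. The median of 23 background probe sets was 3.81, 3.56 and 3.58 after MATR3 siRNA and 3.80, 3.49 and 3.53 after control siRNA. The replicate 1 arrays of both groups stood apart from the other 4. They correlated with each other at r = 0.9955 across clusters and with the other arrays at 0.981 to 0.986. Clusters are not independent replicates.

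The knocked-down gene was lower in every MATR3 siRNA sample than in any control sample. The transcript cluster annotated with MATR3 and its neighbour SNHG4, a host gene of small nucleolar RNA, had log2 signals of 11.21, 10.53 and 10.52 after MATR3 siRNA (mean 10.75 ± 0.40 SD, n = 3). The control signals were 12.25, 11.75 and 11.68 (mean 11.89 ± 0.31 SD, n = 3). The mean pair difference was -1.14 (SD 0.09, n = 3 pairs), which leaves 45.4% of the control signal, with 42.9% to 48.6% in single pairs. An exact two-sided permutation test gave p = 0.1, the smallest that 3 samples against 3 allow. In limma over all clusters the difference had adjusted p = 1 with no block, adjusted p = 0.270 with the replicate number as a block and adjusted p = 0.0547 with the array set as a block. Array weights, another limma option, took it past the threshold at -1.20.

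At exon level the loss was uneven between probe sets. Of 72 kept exon probe sets whose annotation includes MATR3, 38 were at least 2-fold lower after MATR3 siRNA. Their median difference was -2.24, or 21.2% of control. The other 34 were not, with a median difference of 0.06, and they included a probe set more than 2-fold higher, at 1.19. Among the 41 with a control mean of at least 12, 36 were at least 2-fold lower. Ordered by identifier, those of the 41 that did not fall all come before those that fell. The smallest adjusted p among these probe sets in limma with the array set as a block was 0.189. Whether a probe set measures MATR3 or SNHG4 was not analysed here, so the unevenness need not lie within MATR3.

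**Figure D1:**
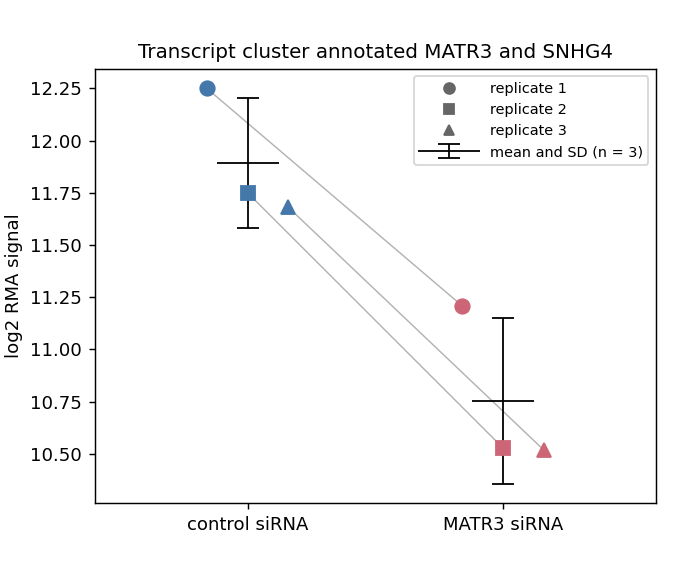
Log2 RMA signal of the cluster annotated with MATR3 and SNHG4 in each of the 6 samples by siRNA, with group mean and SD and lines joining samples of the same replicate number. All 3 MATR3 siRNA samples, at 10.52 to 11.21, lie below the 3 control samples, at 11.68 to 12.25.

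The main question was which genes changed with MATR3 knockdown. With the test fixed before the data were examined (limma, no block), 0 of 33782 transcript clusters passed, with 316 at an unadjusted p under 0.05. The replicate block also gave 0, with 4482 unadjusted. The array set as a block gave 1 cluster, which has no gene symbol and fell by 1.81. Repeated quantile normalization gave the same 1 cluster, and array weights gave 3194 clusters, 2455 higher and 739 lower. Over the 15209 clusters with 1 gene symbol, 0 passed with no block (96 unadjusted) and 8 passed with the replicate block. These 8 were SCN9A, LINGO2 and PRKCA, which rose, and SLC18A1, MIR127, CDH11, SNAR-C3 and GNG8, which fell.

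With the array set as a block over the clusters with 1 gene symbol, a model added after the data were examined, 530 clusters passed in limma. Of these, 316 rose and 214 fell. All 530 moved the same way in the 3 pairs, the median size was 1.35-fold, 100 changed by at least 1.5-fold and 16 by at least 2-fold. The groups did not overlap in 113 of the 530 and in 340 of all 15209 clusters (2.24%). The 10% that chance gives for 3 against 3 exchangeable samples is no measure for either count here, since the replicate 1 arrays stand apart, and the 530 were picked by a test of the same difference. The split into higher and lower depended on the scaling, with 170 and 215 after quantile normalization and 58 and 147 after median centring. Leaving out either replicate 1 sample, of MATR3 siRNA or of control siRNA, amounts to replicates 2 and 3 alone, because the block absorbs the other. In this 1 test the count was 0, with 3776 at an unadjusted p under 0.05. It was also 0 without MATR3 siRNA replicate 3, without control siRNA replicate 2 or without control siRNA replicate 3, and 21 without MATR3 siRNA replicate 2. The replicate 1 set holds 1 sample of each group and allows no test of its own. The genes named as changed from here on passed in this added model, and their changes are log2 means of 3 pair differences with the SD. The highest of the background probe sets averaged 7.17 over the arrays, and 144 of the 530 lay under it in at least 1 group, 108 of them in both. The size and rank of a change that rests on a mean under this level are not exact. Among the genes named with values this holds for 1 group in SLITRK6, GNG8, DBH-AS1, SNAR-C3, SEMA3A and DKK2, and for both groups in ERBB4, LUM, CADPS, NLGN1, INHBA, ITGA4 and TIMP3.

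The 10 largest rises outside the small RNA classes of the naming rule were between 0.93 and 1.49. SLITRK6, a neuronal transmembrane protein, rose by 1.49 ± 0.42 (SD, n = 3 pairs), and PCDH17, a protocadherin of cell adhesion, by 1.38 ± 0.24. SLC39A6, a zinc transporter, rose by 1.06 ± 0.18, and IGFBP3, which binds insulin-like growth factors, by 1.02 ± 0.30. MAZ, a zinc finger transcription factor, rose by 1.02 ± 0.26, and MSI1, an RNA-binding protein of neural progenitors, by 1.01 ± 0.26. ERG28, a sterol synthesis factor, rose by 0.96 ± 0.19, and KCTD12, an auxiliary subunit of GABA-B receptors, by 0.96 ± 0.26. BACE1-AS, annotated as antisense to the beta-secretase gene, rose by 0.95 ± 0.35, and PRKCA, protein kinase C alpha, by 0.93 ± 0.07.

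The 10 largest falls outside the small RNA classes of the naming rule were between -0.89 and -1.41. GNG8, a G protein gamma subunit, changed by -1.41 ± 0.19 (SD, n = 3 pairs), and CDH11, a cadherin, by -1.32 ± 0.11. SLC18A1, a vesicular monoamine transporter, changed by -1.24 ± 0.06, and the long noncoding RNA LINC01963 by -1.23 ± 0.61. DBH-AS1, annotated as antisense to the dopamine beta-hydroxylase gene, changed by -1.12 ± 0.36, and SEPTIN6, a septin of the cytoskeleton, by -1.08 ± 0.21. MFAP4, a glycoprotein of microfibrils, changed by -0.98 ± 0.15, and SNAR-C3, of a family of small noncoding RNAs, by -0.93 ± 0.04. RET, the receptor kinase for GDNF ligands, changed by -0.89 ± 0.11, and CD9, a tetraspanin, by -0.89 ± 0.35. The groups overlapped in SLC39A6, BACE1-AS, PRKCA, MFAP4 and CD9, which the rule as first fixed would have left out. A small SD of pair differences can therefore stand beside wide groups. For PRKCA the group SDs were 0.56 after MATR3 siRNA and 0.50 after control siRNA. Over these 20 genes the adjusted p in limma ranged from 0.0139 to 0.0439. With the replicate block 5 of them passed, PRKCA, GNG8, CDH11, SLC18A1 and SNAR-C3.

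**Figure D2:**
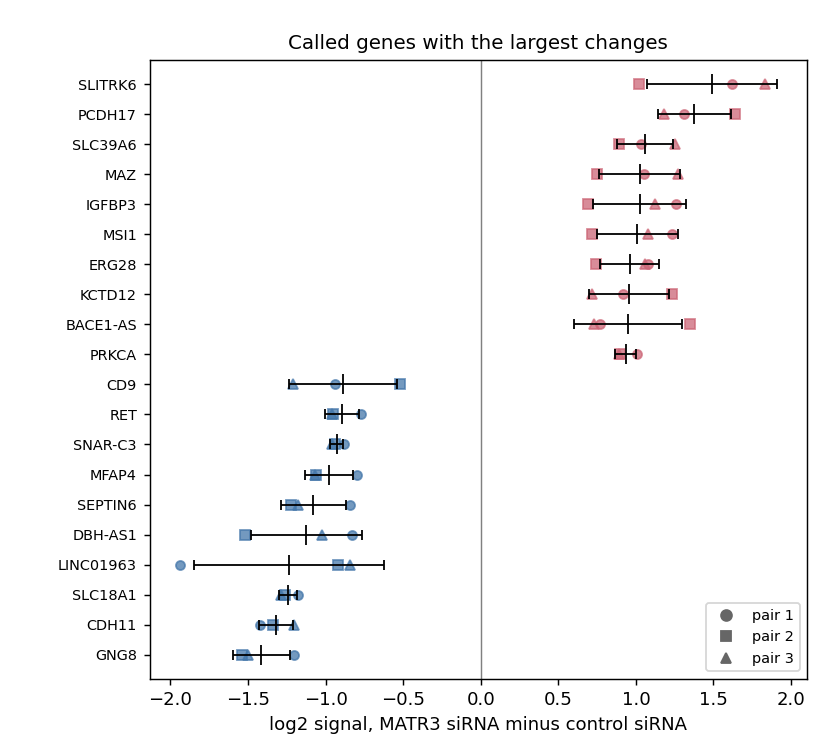
Log2 difference between MATR3 siRNA and control siRNA for the 10 genes with the largest rises and the 10 with the largest falls outside the small RNA classes of the naming rule. Each gene has 1 marker per pair and the mean and SD over 3 pairs. All markers of a gene lie on one side of 0.

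Hypoxia and glycolysis genes were lower as a group. Of 33 measured members, 8 fell, 0 rose and 25 did not pass, and 29 lay below 0. ALDOC, a glycolytic aldolase, changed by -0.88 ± 0.23 (SD, n = 3 pairs), VEGFA, the angiogenic growth factor, by -0.72 ± 0.17, PDK1, a kinase that inhibits pyruvate dehydrogenase, by -0.66 ± 0.09, and SLC2A1, a glucose transporter, by -0.47 ± 0.10. Adjusted over the list alone, 12 fell and 0 rose, and ALDOC was not called after quantile normalization. The list median was -0.12 against 0.04 for all clusters with 1 symbol. Camera gave adjusted p = 1.15e-09 with the preset correlation and adjusted p = 0.354 with an estimated correlation, which loses the call.

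Targets of the tumour suppressor p53 were higher on balance. Of 30 measured members, 6 rose, 0 fell and 24 did not pass, and 21 lay above 0 and 9 below. EDA2R, the ectodysplasin A2 receptor, rose by 0.81 ± 0.27 (SD, n = 3 pairs), TP53INP1, a p53-induced stress protein, by 0.69 ± 0.07, CDKN1A, the cell cycle inhibitor p21, by 0.58 ± 0.10, and ZMAT3, an RNA-binding zinc finger protein, by 0.42 ± 0.12. Adjusted over the list alone, 14 rose and 2 fell, and ZMAT3 was not called after median centring. The list median was 0.20, or 0.16 above that of all clusters with 1 symbol. Camera gave adjusted p = 0.010, and adjusted p = 0.354 with an estimated correlation. Without MATR3 siRNA replicate 1 or without control siRNA replicate 1, the list lay 0.08 above all clusters and camera gave adjusted p = 0.129.

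Genes of sympathoadrenal identity, the lineage of neuroblastoma, moved both ways. Of 26 measured members, 3 rose, 5 fell and 18 did not pass. The 4 largest changes were falls. SLC18A1 changed by -1.24 and RET by -0.89, as given among the largest falls, DBH, which makes noradrenaline from dopamine, by -0.84 ± 0.21 (SD, n = 3 pairs), and DDC, which makes dopamine, by -0.63 ± 0.11. The risers were ISL1 at 0.54, MEIS1 at 0.40, both transcription factors, and STMN2 at 0.37, a stathmin of growing neurites. Adjusted over the list alone, 5 rose and 8 fell. The list median was -0.08, and camera gave adjusted p = 0.010, or adjusted p = 0.550 with an estimated correlation. The camera call was also lost after quantile normalization (adjusted p = 0.0521), after median centring (adjusted p = 0.0624) and without MATR3 siRNA replicate 2 (adjusted p = 0.0926).

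Neuronal cytoskeleton and axon growth genes were lower on balance. Of 36 measured members, 7 fell, 3 rose and 26 did not pass. KIF5C, a kinesin motor, changed by -0.84 ± 0.10 (SD, n = 3 pairs), DPYSL3, of the collapsin response mediators, by -0.59 ± 0.04, and SEMA3A, a repulsive axon guidance cue, by -0.55 ± 0.17. CNTN1, a contactin of neuronal adhesion, rose by 0.57 ± 0.15, and was not called after median centring. Adjusted over the list alone, 9 fell and 4 rose. Camera gave adjusted p = 0.00334, and adjusted p = 0.354 with an estimated correlation.

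Of 31 measured TGF-beta and BMP targets and extracellular matrix genes, 3 fell, 1 rose and 27 did not pass. INHBA, an activin subunit, changed by -0.54 ± 0.22 (SD, n = 3 pairs), the integrin ITGA4 by -0.45 ± 0.03 and TIMP3, an inhibitor of matrix proteases, by -0.38 ± 0.15, while the integrin ITGAV rose by 0.48 ± 0.15 and was not called after median centring. Adjusted over the list alone, 5 fell and 1 rose. Camera gave adjusted p = 0.0114, and adjusted p = 0.354 with an estimated correlation. Without MATR3 siRNA replicate 2, camera gave adjusted p = 0.0615, and with the stricter 75th percentile filter adjusted p = 0.228.

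Cytosolic ribosomal protein genes were slightly higher, with 32 of 35 measured members above 0 and a median of 0.14. Of the 35, 2 rose, 0 fell and 33 did not pass. The risers were RPS18, measured on a cluster of an alternative haplotype, at 0.28 ± 0.05 (SD, n = 3 pairs) and RPL30 at 0.27 ± 0.02. Neither RPS18 nor RPL30 was called after quantile normalization or median centring. Adjusted over the list alone, 4 rose and 0 fell. Camera gave adjusted p = 0.00187, and adjusted p = 0.438 with an estimated correlation. Without either replicate 1 sample, of MATR3 siRNA or of control siRNA, camera gave adjusted p = 0.0877.

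Cholesterol synthesis and uptake genes held 0 that rose and 0 that fell among 26 measured, and 0 adjusted over the list alone, in limma, with 7 at an unadjusted p under 0.05. The 2 brightest were SCD, a fatty acid desaturase, at -0.23 ± 0.24 (SD, n = 3 pairs) and ACLY, which makes acetyl-CoA, at 0.18 ± 0.02. The list median was -0.04, and camera gave adjusted p = 0.0274, or adjusted p = 0.354 with an estimated correlation. This call was absent with no block (adjusted p = 0.0535), with the 75th percentile filter (adjusted p = 0.0958) and with array weights (adjusted p = 0.103). Leaving out 1 sample took it to adjusted p = 0.0744 for MATR3 siRNA replicate 1 or control siRNA replicate 1, adjusted p = 0.0885 for MATR3 siRNA replicate 2 and adjusted p = 0.0618 for control siRNA replicate 3.

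With the fixed model and no block, camera called 6 of the 22 lists, the same lists except cholesterol synthesis, and 0 with an estimated correlation (adjusted p = 0.986 for each) or with fry (adjusted p = 0.993). With the array set as a block camera called 7 lists, 2 higher and 5 lower, and 0 with an estimated correlation. The replicate block also gave 7. With the fixed model, another grouping of the same samples gave 8 lists, as given under the other observations. Fry called 6 with the array set as a block, of which hypoxia, p53 targets and cytoskeleton were among the 7 and synapse, oxidative phosphorylation and Wnt were not. Camera called 4 in replicates 2 and 3 alone, all lower, which is the same test as without MATR3 siRNA replicate 1 or without control siRNA replicate 1, and 4 without MATR3 siRNA replicate 2. Means and camera directions differ in sign for SR proteins, the mesenchymal list, DNA replication and the unfolded protein list, whose medians lie from 0 to the 0.04 of all clusters.

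**Figure D3:**
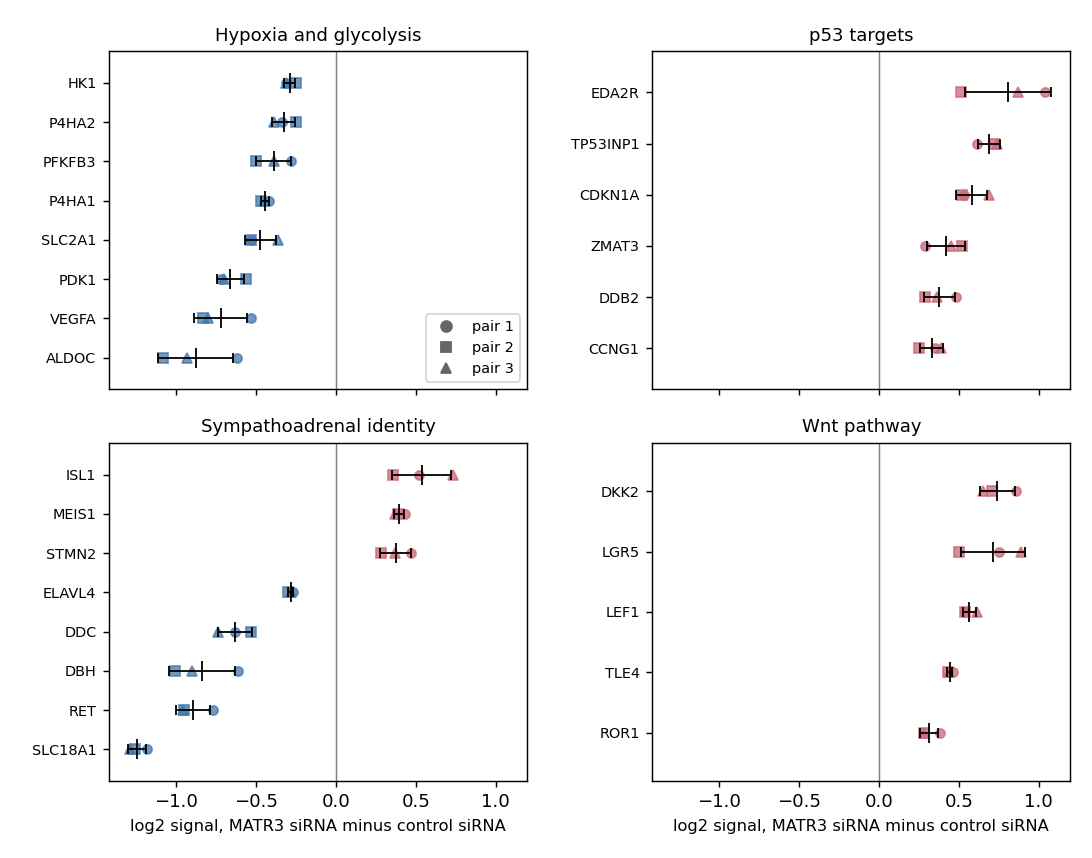
Log2 difference between MATR3 siRNA and control siRNA for the called members of 4 gene lists, with 1 marker per pair and the mean and SD over 3 pairs. The 8 hypoxia and glycolysis genes lie below 0, the 6 p53 targets and 5 Wnt pathway genes above 0, and the 8 sympathoadrenal genes on both sides.

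Camera did not call the other lists (adjusted p from 0.122 to 0.825), though some held changed members. In the Wnt pathway 5 of 30 rose and 0 fell, with 7 and 1 adjusted over the list alone. They included DKK2, a secreted Wnt modulator, at 0.74 ± 0.11 (SD, n = 3 pairs), LGR5, an R-spondin receptor, at 0.71 ± 0.20, LEF1, a transcription factor of the pathway, at 0.56 ± 0.04, and TLE4, a corepressor, at 0.44 ± 0.02. Camera gave adjusted p = 0.138 for Wnt, and fry, which does not compare with other genes, gave adjusted p = 0.000481. With the stricter 75th percentile filter camera called Wnt, at adjusted p = 0.0223, and the list lay 0.12 above all clusters in place of 0.03. Of 37 synapse and vesicle release genes 3 rose and 1 fell, with 7 and 4 adjusted over the list alone. CADPS, which primes dense-core vesicles, rose by 0.80 ± 0.12, NLGN1, a postsynaptic adhesion protein, by 0.45 ± 0.20 and the glutamate receptor GRIA2 by 0.42 ± 0.17, while the vesicle protein SYN1 changed by -0.46 ± 0.14. Of 20 mesenchymal, Schwann or fibroblast markers 3 rose and 1 fell, with 3 and 2 adjusted over the list alone. LUM, a matrix proteoglycan, rose by 0.67 ± 0.18, the intermediate filament VIM by 0.37 ± 0.14 and fibronectin, FN1, by 0.36 ± 0.09, while the annexin ANXA2 changed by -0.83 ± 0.24. After median centring TLE4, SYN1, NLGN1, GRIA2, LUM, VIM and FN1 were not called.

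Cell cycle and growth factor genes changed in few members. Of 43 G2/M and mitosis genes 2 rose and 0 fell, ANLN at 0.51 ± 0.12 (SD, n = 3 pairs) and PRC1 at 0.48 ± 0.22, both of cytokinesis, with 2 and 1 adjusted over the list alone. Of 40 DNA replication genes 0 rose and 0 fell in limma, with 0 adjusted over the list alone and 9 at an unadjusted p under 0.05, and the brightest were TYMS at 0.09 ± 0.08 and MCM3 at 0.05 ± 0.02. Of 30 immediate early genes 1 rose and 2 fell, with 2 and 3 adjusted over the list alone. SPRY1 and SPRY2, feedback inhibitors of receptor kinase signalling, changed by -0.67 ± 0.26 and -0.55 ± 0.22, and CCND1, cyclin D1, rose by 0.28 ± 0.06. Of 19 replication-dependent histone genes 0 changed over all in limma, 3 rose adjusted over the list alone and 5 had an unadjusted p under 0.05, with H1-4 at 0.19 ± 0.02 and H2AC20 at 0.03 ± 0.11. After median centring ANLN, PRC1 and CCND1 were not called.

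Few members passed in the lists of hnRNP proteins, splicing regulators, ALS-linked genes and RNA decay factors. Of 26 PTB, hnRNP and paraspeckle proteins 0 rose and 0 fell in limma, with 0 adjusted over the list alone and 2 at an unadjusted p under 0.05, and the brightest were NONO at 0.09 ± 0.08 (SD, n = 3 pairs) and HNRNPM at -0.07 ± 0.06. Of 42 SR proteins and splicing regulators 1 rose, NOVA1, a neuronal splicing factor, at 0.36 ± 0.12, with 2 higher and 1 lower adjusted over the list alone. Of 24 ALS-linked genes 1 rose, ERBB4, a neuregulin receptor, at 0.70 ± 0.16, with 2 higher adjusted over the list alone. Of 18 nonsense-mediated decay factors and targets 1 rose, SMG9 at 0.32 ± 0.09, with 2 adjusted over the list alone.

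In the remaining lists, 1 of 43 oxidative phosphorylation genes rose, COX6A1 at 0.32 ± 0.06 (SD, n = 3 pairs), with 0 adjusted over the list alone. Of 36 autophagy and lysosome genes 1 rose, HEXA, a lysosomal hexosaminidase subunit, at 0.46 ± 0.06, with 1 adjusted over the list alone. Of 39 unfolded protein and ATF4 response genes 1 fell, the chaperone cofactor DNAJC3 at -0.36 ± 0.04, with 2 higher and 2 lower adjusted over the list alone. Of 15 interferon response genes 0 changed in limma, with 1 lower adjusted over the list alone and 1 at an unadjusted p under 0.05, and the brightest were IFI6 at 0.26 ± 0.30 and IFIT5 at 0.09 ± 0.17. NOVA1, SMG9, COX6A1, HEXA and DNAJC3 were not called after median centring.

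The splicing comparison asked which exons changed beyond their gene. With the fixed test (limma, no block), 0 of 456623 probe sets changed in signal, with 16799 at an unadjusted p under 0.05 and 30 calls with array weights. For the splicing index 0 of 347254 probe sets passed, with 17620 unadjusted. DiffSplice on the same probe sets called 415, 175 higher and 240 lower. It pools the variance over all probe sets of a gene, so that probe sets on the same arrays count like replicates. Without MATR3 siRNA replicate 1 the splicing index test called 489. That fit keeps control siRNA replicate 1, which stood apart, without its counterpart in the other group. The same test called 0 without control siRNA replicate 1 and 0 in replicates 2 and 3 alone. With the replicate block it called 1, a junction of IBTK, an inhibitor of Bruton's tyrosine kinase, whose index changed by -7.94. Its log2 signals were 5.85, 2.24 and 4.30 after MATR3 siRNA and 13.74, 9.53 and 12.87 after control siRNA. All 3 MATR3 siRNA signals lie under the 7.17 of the highest background probe set, so the size of this change is not exact, and the junction was at least 4.875 lower when set against that level. The other 79 probe sets of IBTK had a median change of 0.13.

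With the array set as a block and exon probe sets alone, a model added after the data were examined, 15 of 195458 exon probe sets in 11 genes had a changed splicing index in limma (adjusted p = 0.0405 for each), 8 higher and 7 lower. Higher indices were found in CHD1L, a chromatin remodeller, at 3.20 ± 0.66 (SD, n = 3 pairs), GRK4, a G protein-coupled receptor kinase, at 2.92 ± 0.91, COA1, a mitochondrial assembly factor, at 2.28 ± 0.37, and TTLL5, a tubulin glutamylase, at 1.99 ± 0.19. Lower indices were found in DTX2, a ubiquitin ligase, at -2.48 ± 0.56, AK4, a mitochondrial adenylate kinase, at -2.01 ± 0.19, and GRK5 at -1.18 ± 0.08. The calcium channel subunit gene CACNB2 held 1 probe set at 2.29 ± 0.56 and 1 at -1.24 ± 0.05. NTNG1, a netrin-related adhesion protein, held 1 at 1.80 ± 0.28 and 1 at -1.82 ± 0.18. TTN-AS1, annotated as antisense to the titin gene, held 1 at 1.78 ± 0.33 and others at -2.15 ± 0.55 and -2.56 ± 0.37. In CDH11, which fell at gene level, 1 exon probe set had an index of 2.03 ± 0.32. Its own signal differed by 0.46, against -1.57 for the mean of the gene's exon probe sets. In 7 of the 15 the probe set's mean in 1 group lay under the 7.17 of the highest background probe set, in CHD1L, GRK4, DTX2, the higher index of CACNB2 and of NTNG1 and both lower ones of TTN-AS1, so that the sizes of these indices are not exact.

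The number of splicing index calls depended on the model. DiffSplice called 1678 in the same exon probe sets, while subtracting the gene-level value gave 1, the 75th percentile filter gave 2 (COA1 and CDH11), and subtracting the median, including junctions or omitting the trend and robust options gave 0. The count was 25 without MATR3 siRNA replicate 2, 1 without control siRNA replicate 2, 0 without MATR3 siRNA replicate 3 or without control siRNA replicate 3, and 0 in replicates 2 and 3 alone, which had 33577 at an unadjusted p under 0.05. Leaving out either replicate 1 sample, of MATR3 siRNA or of control siRNA, is nearly that same test and also gave 0.

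**Figure D4:**
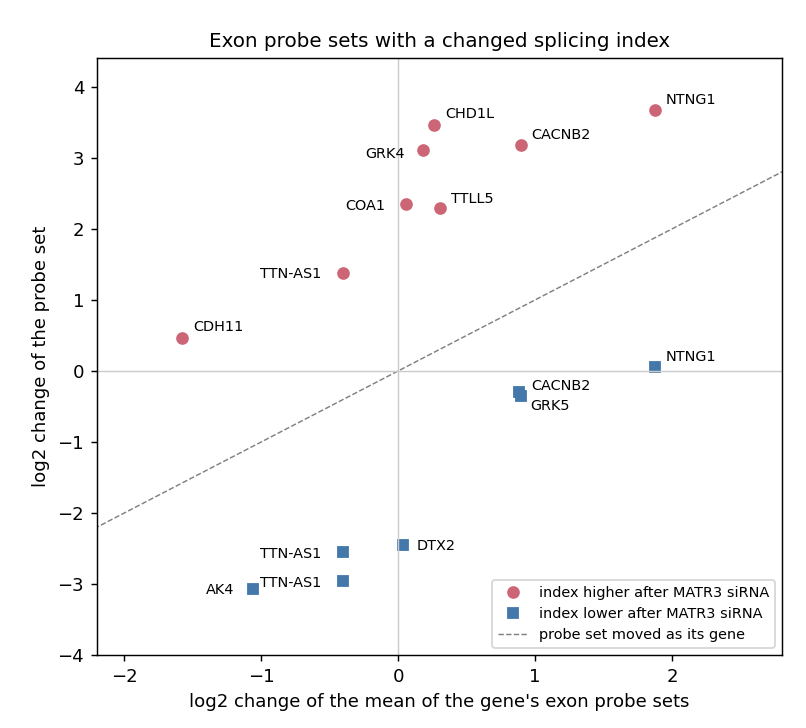
Log2 change of the probe set against the log2 change of the mean of its gene's exon probe sets, for the 15 exon probe sets with a changed splicing index, labelled by gene. Points above the dashed line of equal change have a higher index after MATR3 siRNA and points below it a lower one.

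Of the 9 genes recalled from earlier work on MATR3-dependent exons, 6 had kept exon probe sets, 141 in all (ABI1, ACSL3, PIGX, PLEKHA3, PTBP2 and TCF12). In limma with the array set as a block 0 of these passed, either adjusted over the list alone or over all, and 15 (10.6%) had an unadjusted p under 0.05, as did 19412 (9.93%) of all 195458 in the same model. The list may have been chosen on these samples and is not independent evidence. The probe set with the lowest unadjusted p in each gene was at 1.20 ± 0.76 (SD, n = 3 pairs) in PIGX, of glycosylphosphatidylinositol anchor synthesis, and at 0.96 ± 0.52 in ACSL3, a fatty acid CoA ligase. It was at 0.62 ± 0.83 in ABI1, at 0.60 ± 0.46 in PLEKHA3, at 0.57 ± 0.52 in PTBP2, the neuronal PTB protein, and at 0.56 ± 0.31 in TCF12, a transcription factor.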

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

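The models with the array set as a block, the use of replicates 2 and 3 alone and the combinations with them were chosen after the data were examined. With that block, leaving out either replicate 1 sample and using replicates 2 and 3 alone are the same test, or nearly so for the splicing index, and the totals below count it 3 times. No result changed direction in a called value under any alternative run. Of 147 alternative counts or main values, 95 stayed on the same side of the threshold or within 1.5 times, 18 were higher or newly past it and 34 lower or no longer past it. For single gene changes 466 of 1086 alternatives kept the call or its absence, 3 gained a call and 617 lost it or, in genes not called, changed sign. For list shifts it was 296 of 330, with 1 gained and 33 lost or, in lists not called, changed in sign. For single splicing indices 82 of 212 kept the call and 130 lost it.

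With the fixed tests, the count of changed clusters (0) became 1 with quantile normalization, 1 with the array set block, 3194 with array weights, 8 with the replicate block and 1 symbol, and 530 with the array set block and 1 symbol. The MATR3 cluster kept -0.96 to -1.37 with single samples left out and passed with array weights at -1.20. The 6 shifted lists became 0 with an estimated correlation and 0 with fry. Changed probe sets (0) became 30 with array weights. Splicing index calls (0) became 415 with diffSplice, 1 with the replicate block, 15 and 17 with the array set block or the replicate block plus exon probe sets, trend and robust options, and 0 to 489 with single samples left out. With the replicate block the lists also went from 6 to 7, and it changed no other call of the fixed tests.

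In the added model the 530 clusters became 100 with a 1.5-fold minimum, 1 over all clusters, 124 with no filter, 973 with the 75th percentile filter, 836 with trend and robust options, 205 with median centring, 3275 with array weights, 8 with the replicate block, 0 to 21 with single samples left out, 0 in replicates 2 and 3 alone and 0 with no block. Quantile normalization gave 385, of which 355 were among the 530. The 7 lists became 0 with an estimated correlation, 4 to 7 with single samples left out and 4 in replicates 2 and 3 alone. The 15 splicing index calls became 1678 with diffSplice, 1 with the gene-level value subtracted, 0 with the median subtracted, 0 with junctions, 0 without trend and robust options, 0 with no filter, 2 with the 75th percentile filter, 9 with quantile normalization, 26 with array weights, 0 to 25 with single samples left out, 0 in replicates 2 and 3 alone and 0 with no block. Stricter filters, extra features and left-out samples change how many features or samples are tested; for the other settings the cause was not tested. Signal over background limits dim features, since only 16.3% to 26.2% of clusters per array lay above the highest background probe set.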

Other observations

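The tests of the catecholamine genes, of the splicing index and of small RNA yield, and the counts over other splits of the samples, were chosen after their results were seen; the test of the whole DLK1 to DIO3 region was written before, though the region itself was picked from the calls.

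MicroRNA and small nucleolar RNA genes fall outside the rule for named genes, the SNAR genes do not, and both were looked at after their values were seen. In limma with the array set as a block, 6 of 49 measured clusters of the imprinted DLK1 to DIO3 region fell and 0 rose, in a region that holds 122 genes in the RefSeq table of GRCh38.p14. These were MIR432 at -1.25 ± 0.51 (SD, n = 3 pairs), MIR431 at -1.24 ± 0.42, MIR127 at -1.10 ± 0.08, MIR136 at -1.07 ± 0.34, SNORD114-15, and RTL1, a retrotransposon-derived gene of the region, at -0.80 ± 0.15. Both means of SNORD114-15, 5.04 and 5.54, lie under the 7.17 of the highest background probe set, so its change has no exact size. Of the 5 measured microRNA clusters inside the span of RTL1, all 5 were lower and 4 were called. The other was MIR433, at -0.82 ± 0.45 with adjusted p = 0.0533. DLK1 itself was at -0.33 ± 0.19 and did not pass. SNAR-C3, SNAR-C4 and SNAR-E, 3 of 5 measured small NF90-associated RNAs, fell at -0.93 ± 0.04, -0.87 ± 0.17 and -0.73 ± 0.18, with MATR3 siRNA means under that level, and both others were lower without passing. NPY, a neuropeptide of sympathetic neurons, also fell, at -0.86.

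SLC18A1, RET, DBH and DDC fell together. Fewer noradrenergic cells in the dishes would lower the sympathoadrenal list as a whole. Of its 26 measured members 15 lay below 0 and 11 above. The called risers ISL1, MEIS1 and STMN2 stayed above 0 by more than 2 SE after quantile normalization and after median centring. This does not decide, because these 3 were picked as called higher in the same model and the bar of 3 was set afterwards. Fewer such cells as a source of the falls, in whole or in part, stays open. The scale of the arrays is argued against by the change of the least lowered of the 4 after quantile normalization, -0.67 (SE 0.07). A change in the expression of these genes with MATR3 knockdown may remain as a hypothesis, and an effect of the siRNA apart from MATR3 was not tested.

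A splicing index can move because the gene changes past a probe set that stays put. The gene mean would then move against the index by its whole size, a share of 1. Over all 15 calls the median share was -0.0628 (SD 0.56), and in 9 the gene mean moved the same way as the index. This does not decide on the 15 as a set. The gene mean includes the probe set itself, which pulls it the same way, and 7 indices rest on a mean under the highest background probe set. In COA1, TTLL5, AK4 and the higher index of TTN-AS1 both means lay above that level. There the share was -0.027, -0.15, -0.53 and 0.225, which argues against that source for these calls. The size of the probe sets' own changes, looked at first, did not decide, with a median of 1.35 (SD 1.05) when group means under the highest background probe set are raised to its 7.17. By the values as given, the probe set moved more than the gene mean in 11 calls. The median absolute change of these gene means was 0.40, and the share was at most 0.225. With means raised to 7.17, the probe set of the higher CACNB2 index moved by 0.718, less than its gene mean at 0.894. The share was 0.72 to 1.03 in the other 4, of CDH11, GRK5, CACNB2 and NTNG1. In these the probe sets moved by a median of 0.325 and the gene means by 1.23, and that source stays open. Because these 4 were picked for that property, an exon that kept its level through a splicing change cannot be told apart from a probe set that does not follow its gene.

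For the DLK1 to DIO3 region, the 43 clusters that were not called had a median change of -0.00333 (SD 0.28). This decides nothing on a lower level of the whole region, because the called clusters are left out and 40 of the 43 do not exceed the highest background probe set. The 3 that do, MIR433, DLK1 and SNORD114-28, were all lower. Elsewhere, 241 of 629 clusters of microRNAs and small nucleolar RNAs exceed that background level, with a median change of 0 (SD 0.28). This cannot decide on a lower yield of small RNA in the MATR3 siRNA preparations. Whether these clusters read small RNAs or longer transcripts that contain them was not analysed. A lower level of the whole region and a lower level around RTL1 alone, whose span holds 4 of the 6 called clusters, cannot be told apart. Strand was not used in placing clusters inside that span, so whether RTL1 and these clusters share a transcript was not analysed. Whether the probes read microRNA precursors or other transcripts of the span was also not analysed here.

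The 6 samples can be split into 3 against 3 in 10 ways, too few for a share under 0.05. For transcript clusters with the fixed test, all 10 splits gave as many calls as the real one, which gave 0, and the highest other gave 0. For lists with the fixed test 3 of the 10 gave at least the real 6, with 8 in the highest other. For probe sets the real split gave 0 and the highest other 1, and for the splicing index the real split gave 0 and the highest other 6, so that all 10 gave as many. For the clusters with 1 symbol and the array set as a block, only 1 split, the real one, gave 530, and the highest other gave 0. For lists with that block 2 splits gave at least 7, with 8 in the highest other, and for the added splicing index model 1 split, the real one, gave 15, with 3 in the highest other. Among the 4 splits that part all 3 pairs, the highest other gave 8 lists with the fixed test, 5 lists with the block, 0 clusters with 1 symbol and 0 splicing index calls. The added models were chosen out of 30 and 24 after their counts on the real split were seen. Their comparison with other splits therefore favours the real split and decides nothing. For lists with the fixed test, other splits called as many as the real one or more. The count of called lists therefore does not set the real split apart there. Splits that put both replicate 1 arrays in the same group also overlap with the block. For the IBTK junction, 2 probe sets differed by over 4 log2 in all 3 pairs in the real split, and 2 to 6 did in the other 3 splits that part the pairs.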
